A study of Mus musculus with 12 samples.

How the data were processed

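ATAC-seq measures where a transposase can insert into chromatin, and the labels describe the libraries as nucleosome-free chromatin of sorted mTEChi. The thymus was digested with enzymes and the cells were sorted before library preparation, per the labels' protocols. The submitters' processing notes name cutadapt, Bowtie2, Picard, MACS2 and the mouse build mm10, without versions or order. Each library had its own list of peaks, so peaks were called per sample. Peaks were deposited as broad peaks for 8 libraries, with a score, the fold enrichment over background, and −log10 p and −log10 q per peak, as the authors' caller gave them. In these files the deposited score equals 10 times −log10 q, with a difference of at most 1 in 1 to 6 peaks per list, and the lowest −log10 q lies just above 1. The 4 lists of the C313Y contrast, as deposited by the authors, hold positions only. Thus their threshold, score and p could not be examined, and peaks there were ranked by width. A peak's fold and rank are the authors' values and were used within one list only. Read shifting, duplicate removal and any control library are not given in the sources used here.

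No read counts were used, so depth is unknown, and a longer list can reflect more reads, a better signal or more open chromatin. The number of peaks per library is given as the only trace of depth. Where depth or signal differs between 2 lists, weak peaks pass the caller's threshold in one and not in the other. Absence of a peak therefore means not called at that depth. Only 2 libraries per group limit every comparison, and where the labels do not name separate animals the spread measured here may be technical.

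Libraries were grouped by title and genotype. Wild types carry the same genotype label, and each pair was matched to a mutant by the shared form of the titles, which is an assumption. Peaks on chromosomes 1 to 19 and X were kept. Within each contrast all peaks were merged into regions where they overlapped by at least 1 bp, and a library had a region when its peaks overlapped it by at least 1 bp. Genes were the 21631 protein-coding genes of the RefSeq table for GRCm38.p6, which shares coordinates with mm10. The table used gives no strand and no exons. A peak within 1 kb of either annotated end of a gene was therefore counted, in place of the start of transcription planned, and positions were classed as near a gene end, inside a gene or between genes. Introns, exons and untranslated parts were not told apart. Neighbouring genes can share a peak, and the peaks of 1 gene in 2 libraries need not overlap or lie at the same end.

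Gained and lost were defined by presence in both libraries of one group and neither of the other. Peak number, covered length and median width were compared as log2 ratios by exact two-sided permutation tests, within contrasts (6 assignments) and over the 3 contrasts with labels permuted within each (216 assignments, smallest p = 0.00926). Gene groups were 28 lists fixed before the data were examined, 17 by symbol and 11 by name pattern. All members matched except Mx1 of the interferon-induced list. Each list was tested by Fisher's exact test, two-sided, against the genes that could have been gained (no peak in either wild type) or lost (a peak in both), with Benjamini-Hochberg adjustment over 168 tests. Overlaps between contrasts used Fisher's exact test on merged regions, with the expected number from independent sets and with the ratios of mixed pairings. Odds ratios of same against opposite direction had 0.5 added to each cell. Regions and genes are not replicates, and these p-values describe these libraries. Jaccard indices were computed in base pairs.

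Genes named in the text were taken by a rule fixed before the data were examined: Aire, then per contrast the 10 gained and 10 lost genes with the highest rank, and of each list up to 4 gained and 4 lost members. The rank is the lower of the 2 libraries' percentiles of the strongest peak by −log10 p, or by width in the C313Y contrast. Some genes this rule selected are not reported here. Alternatives were a −log10 q of at least 3, lists of equal length (the strongest N peaks, N being the shortest list of a contrast), other overlap rules, fixed windows of 500 bp, gene windows of 500 and 2500 bp, presence in 1 library, all 6 wild types as controls, other backgrounds, each replicate left out and a replicate block. Gene bodies, autosomes only and the widest N peaks for C313Y were added after seeing the data, as were comparisons between contrasts that joined these to the strongest N peaks of the other 2, and exact permutation tests of single genes and regions over the 3 contrasts.

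The counting was tested on simulated lists made from 1 wild-type list per contrast with 15% of peaks dropped at random in each library, 100 genes planted as gained and 100 as lost among 21631. In the knockout contrast 74% of planted gains and 75% of planted losses were recovered, in C313Y 69% and 76%, and in C442G 71% and 75%. Most planted gains were olfactory receptor genes. Recovery is set largely by the dropout rate, so it checks the counting only. Random dropout alone gave 176 gained and 137 lost genes elsewhere in the knockout simulation, 163 and 195 in C313Y and 168 and 165 in C442G. At this dropout the real losses (6, 80 and 63) lay below these counts and the gains in C313Y and C442G (183 and 194) little above. Simulated peaks were dropped regardless of strength, whereas weak peaks are those that fail a caller's threshold. The simulated counts are therefore not a baseline for the real ones. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6, and figures matplotlib 3.10.9.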

Results

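Accessible chromatin was profiled by ATAC-seq in mature medullary thymic epithelial cells with high surface expression (mTEChi), sorted from C57BL/6 mice of 4 to 7 weeks. These cells express AIRE, the autoimmune regulator, which drives ectopic expression of tissue-restricted antigens in the thymus. The 12 libraries formed 6 groups of 2: Aire-deficient mice (Aire -/-), heterozygotes for the AIRE missense changes C313Y and C442G, and for each of these 3 genotypes its own pair of Aire +/+ wild types. The data were 1 list of accessible regions (peaks) per library, without read counts, so the sequencing depth behind each list was unknown. Over chromosomes 1 to 19 and X the lists held 34047 to 122326 peaks and covered 7.04 to 30.3 Mb. A region or gene was called gained when both mutant libraries and neither wild-type library had a peak there, and lost in the reverse case. Within a contrast of 2 libraries against 2 no single region or gene can pass a test, so the counts of each contrast were set beside those of the other 2 ways of pairing its 4 libraries.

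The Aire gene (chromosome 10, 78030022 to 78043610, mm10) was accessible at one end in every genotype. A region at 78043452 to 78043805, across the annotated gene end, had a peak in 12 of 12 libraries, the knockout included. In the 2 wild types of the knockout contrast its −log10 q was 2.69 and 2.97, under the stricter threshold of 3 used as an alternative. Peaks at this end cannot check the knockout label, because the lists do not show which part of the gene was removed. A region that starts 2584 bp beyond this end, at 78046194 to 78047024, and one on the other side of the gene, at 78018652 to 78019119, were also called in all 12. A further region at 78028165 to 78028486 was called in 11 of 12. An enhancer that responds to NF-kB is known upstream of Aire, and the identity of the region beyond the gene end was not tested. Its peaks were 658.5 bp wide on average in knockout libraries against 272.5 bp in their wild types, 691.5 against 508.5 bp in the C313Y contrast and 806 against 615 bp in the C442G contrast (n = 2 per group). Inside the gene no region was called in more than 2 libraries.

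**Figure D1:**
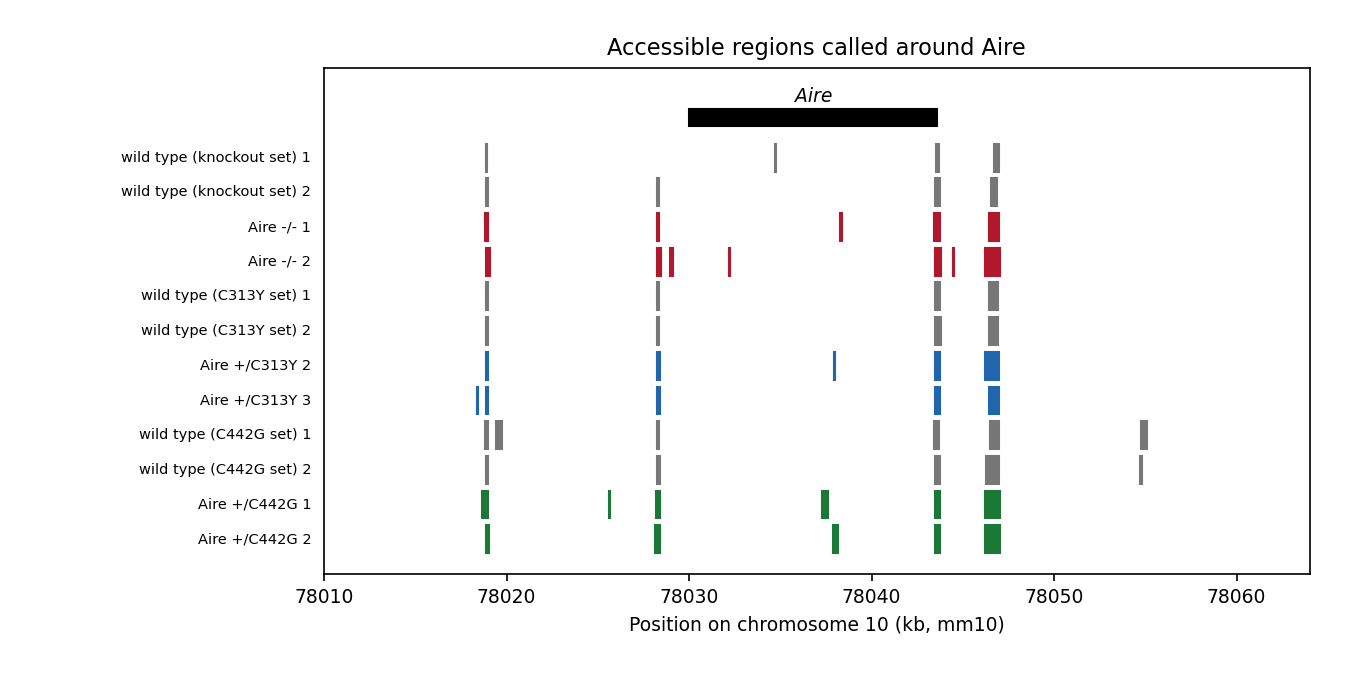
Peaks of the 12 lists around Aire, 1 line per library, on chromosome 10 in kb (mm10). The black bar is the annotated gene, grey boxes are peaks of wild-type libraries and coloured boxes those of Aire mutants; 3 regions outside or at the end of the gene were called in all 12 libraries.

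How the total of accessible regions differed with Aire genotype was asked of the lists first. Aire-deficient cells had 90401 ± 6470.03 peaks (SD, n = 2) and their wild types 34381 ± 472 (n = 2), a 2.63-fold ratio. C442G heterozygotes had 118680 ± 5156 peaks against 94058.5 ± 565 in wild types, 1.26-fold more. C313Y heterozygotes had 66555 ± 13117 and their wild types 64918.5 ± 12809, a ratio of 1.03 that lay within the spread between replicates. Within a contrast the exact two-sided permutation test cannot go below p = 0.333, the value reached for the knockout and C442G (C313Y, p = 0.667). Over the 3 contrasts, with labels permuted within each, mutants exceeded wild types by 0.59 on the log2 scale (exact permutation p = 0.0370, adjusted p = 0.0556 over 3 measures by Benjamini-Hochberg), which did not pass correction. Covered length gave 0.62 (exact permutation p = 0.0185, adjusted p = 0.0556) and median peak width 0.05 (p = 0.454). Without C313Y heterozygote replicate 2, or without wild-type replicate 2 of that contrast, the test on peak number gave an exact permutation p of 0.130. Wild-type lists also differed among contrasts, from 34715 and 34047 peaks in the knockout contrast to 93659 and 94458 in the C442G contrast.

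**Figure D2:**
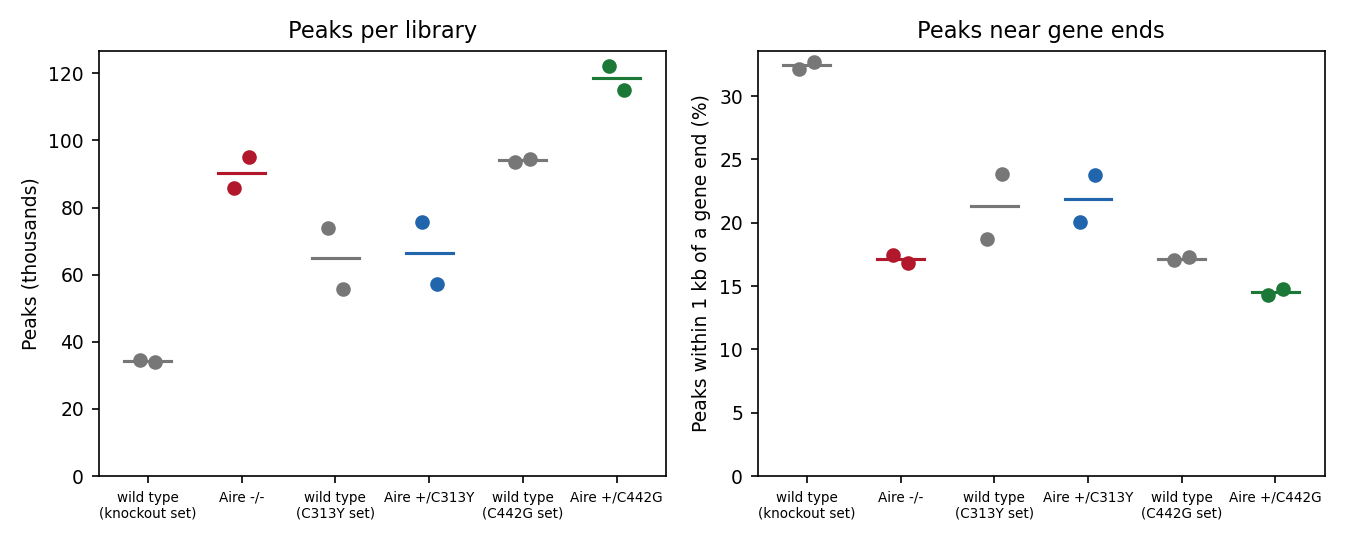
Number of peaks, in units of 1000 (left) and percentage of peaks within 1 kb of an annotated gene end (right) in each library. Points are libraries, lines are means of 2 libraries, grey marks wild types and colours mark Aire mutants; the 2 wild-type libraries of the knockout contrast had the fewest peaks and the highest share near gene ends, 32.2% and 32.7%.

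In Aire-deficient cells 1128 protein-coding genes gained a peak within 1 kb of a gene end and 6 lost one. The gained genes whose peaks ranked highest within both knockout lists were S1pr4, a receptor for sphingosine-1-phosphate, the fatty acid transporter Slc27a1, the lysophospholipase Pnpla6, the serine protease Tmprss9 and Rnf212, which acts in meiotic recombination. Other genes that ranked high were the transcription factor Sp2, the zinc finger gene Zfp952, Tex9 and Elovl1, an elongase of very long fatty acids. The S1pr4 peak (chromosome 10, 81496327 to 81496837 in replicate 1) lay within 1 kb of the gene (81497745 to 81500137). It carried the authors' fold enrichments of 10.3 and 12.1 in the 2 knockout lists and stood above 98.3% and 98.8% of the other peaks there. At Slc27a1 (chromosome 8, 71568728 to 71587307) a peak at 71569525 to 71570762 had folds of 6.98 and 7.40. Slc27a1, Pnpla6, Sp2, Zfp952 and Tex9 had a peak in all 4 wild-type libraries of the other 2 contrasts, while S1pr4 had one in 1 of these 4. The lost genes included Glrb, a glycine receptor subunit, the receptor kinase Ephb2, caldesmon Cald1, the cation channel Trpv3 and Zfp541. Glrb ranked highest of these, with folds of 3.90 and 4.18 in the 2 wild-type lists.

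Genome-wide, Aire-deficient cells gained 25625 regions and lost 107, and 21221 regions were shared by all 4 libraries. The other 2 pairings of the same libraries gave 1508 and 1413 regions in both directions together, against 25732 for genotype. Genes came to 1134 against 113 and 100. When every list was reduced to its 34047 strongest peaks, 3791 regions were gained and 1662 lost, with 2026 and 1959 for the other pairings, and genes turned to 173 gained and 339 lost. Of the gained regions and genes, 3348 regions and 53 genes had no peak in any of the 6 wild-type libraries. Replicate 2 of the knockout and replicate 2 of its wild type had peaks at 4 and 3 of 4 Y-linked genes and both replicates 1 at 0, so sex-linked signal followed the replicate number here and not genotype.

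Among gene groups, chemosensory receptor genes were gained less often than other genes in the knockout. Of 1097 olfactory receptor genes without a peak in either wild-type library, 10 were gained (0.912%, against 11.8% of all 9597 such genes; Fisher's exact test, adjusted p = 4.38e-46). Most of this family had no peak in any library (1032 of 1110). Those with a peak still rose, from 10 and 7 in wild types to 23 and 26 in the knockout. Mixed pairings did not pass (Fisher's exact test, adjusted p = 0.535 and 0.362), but with few gained genes (42 and 30) they could hardly show a shortfall. Of 351 vomeronasal receptor genes 2 were gained (Fisher's exact test, adjusted p = 6.62e-15), a difference that did not pass with lists of equal length (0 gained, adjusted p = 0.105). These p-values take genes as units and describe these libraries. Keratin-associated proteins (0 of 53, Fisher's exact test, adjusted p = 0.0515) and defensins (1 of 67, adjusted p = 0.0698) did not pass. Neither did any other list, in either direction. Aire-induced tissue antigens gained 2 of 18, Chrna1, a muscle acetylcholine receptor subunit, and the neuropeptide gene Npy. Antigens independent of AIRE or dependent on Fezf2 gained 2 of 8, the casein Csn2 and the calcium-binding protein gene Calb1. Genes of mTEC identity and antigen presentation gained 2 of 10, the chemokine Ccl17 and the costimulator Cd86, and corneocyte-like cells that follow the Aire stage gained 3 of 8, Dsg1a, Grhl3 and Krtdap. Thymic tuft cell genes gained 2 of 9 (Trpm5 and L1cam), other mimetic cell genes 1 of 7 (Ptf1a), keratins 7 of 44, homeobox cluster genes 6 of 29, cytochromes P450 5 of 65, zinc finger genes 15 of 101, serpins of clades A and B 3 of 43 and caseins 1 of 5. Of the members named here, Calb1, Ccl17, Cd86, Krtdap, Trpm5 and Ptf1a had a peak in all 4 wild-type libraries of the other 2 contrasts. Chrna1, Npy, Csn2, Grhl3 and L1cam had one in 3 of these 4, and Dsg1a in 2. Major urinary protein genes gained 0 of 22. At equal list length most of these gains went: keratins gained 1 of 44, serpins 1 of 45, zinc finger genes 4 of 103 and the other lists of genes named here 0, while corneocyte-like genes lost 2 of 5 (Fisher's exact test, adjusted p = 0.213).

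Markers of other cells of the thymus were also among the genes gained in the knockout, and none of these lists passed the test. Dendritic cell and macrophage genes gained 3 of 10, among them Clec9a, a receptor of cross-presenting dendritic cells, with folds of 6.56 and 7.00. Thymocyte and T cell genes gained 2 of 14 (Cd4 and Lat), B cell genes 1 of 6 (Vpreb3), fibroblast and mural genes 1 of 7 (Fbn1), cortical epithelial genes 1 of 5 (Enpep) and endothelial genes 0 of 8. Dendritic cell and macrophage genes gained 1 of 10 with lists of equal length, and the other 5 of these lists 0. Most genes of some groups were open throughout. Of 22 reported AIRE partner genes 20 had a peak in all 12 libraries, as did 19 of 21 NF-kB pathway genes, 24 of 28 constitutively expressed genes, 12 of 17 interferon-induced genes and 10 of 17 genes of chromatin insulation and polycomb. In the knockout the partner gene Xrcc6, the interferon-induced genes Gbp2 and Oas1a and the constitutive gene Ywhaz were gained. Cd4, Enpep, Gbp2 and Oas1a had a peak in all 4 wild-type libraries of the other 2 contrasts. Clec9a, Lat, Fbn1 and Xrcc6 had one in 3 of these 4, Ywhaz in 2 and Vpreb3 in 1. Zfp541 was the one lost member of any list.

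**Figure D3:**
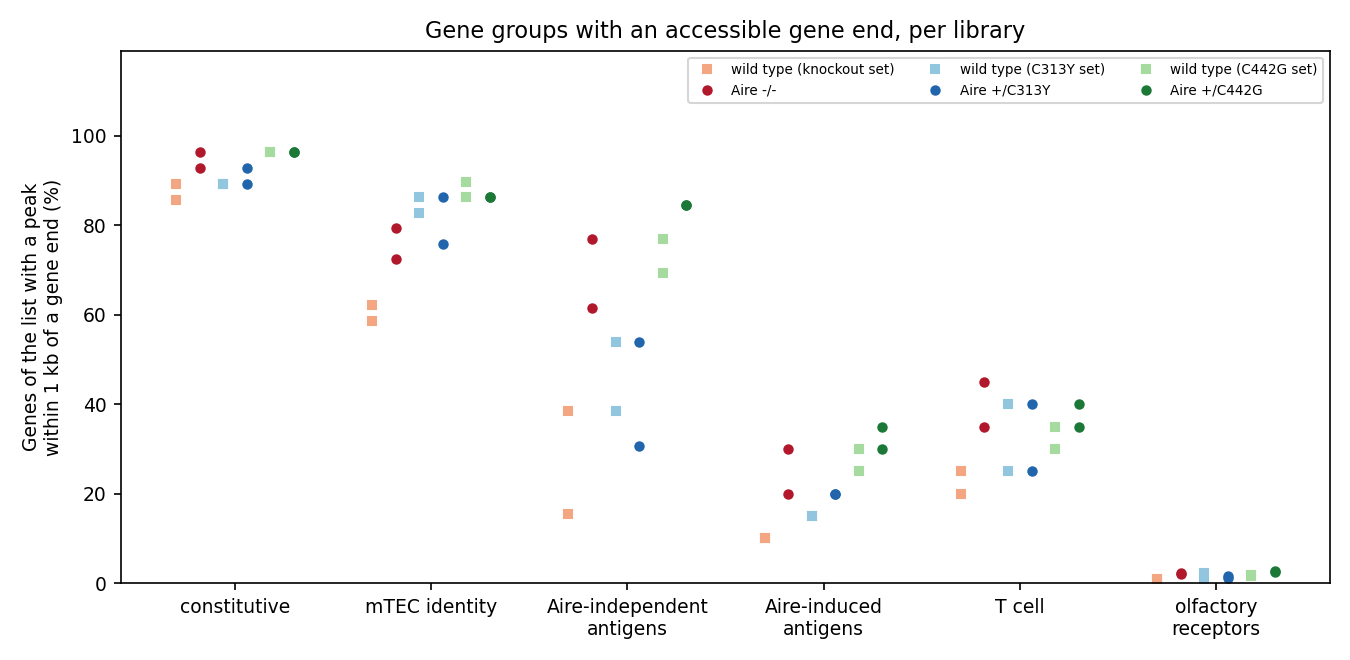
Percentage of the genes of 6 lists with a peak within 1 kb of a gene end, in each library. Squares are wild-type libraries and circles Aire mutants, coloured by contrast, with coinciding points drawn over each other; olfactory receptors stayed between 0.631% and 2.61% in all libraries, and Aire-induced antigens between 10% and 35%.

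The regions gained in Aire-deficient cells lay away from gene ends more often than regions shared by all 4 libraries. Of the gained regions 7.90% lay within 1 kb of an annotated gene end, 50.3% inside genes and 41.8% between genes. Among regions shared by all 4 libraries 44.8% lay near gene ends (odds ratio 0.106, Fisher's exact test across regions, with a p-value under the smallest number the software stores). The 107 lost regions had 15.9% near gene ends (odds ratio 0.233 against shared regions, Fisher's exact p = 4.50e-10). With lists of equal length 8.36% of gained and 23.3% of lost regions lay near gene ends, and mixed pairings lay between, at 11.6% to 13.5%. Of all peaks, 17.5% and 16.8% lay near gene ends in the knockout lists and 32.2% and 32.7% in their wild types. The C442G wild types, at 17.0% and 17.3%, were close to the knockout lists. The median width of gained regions was 183 bp, that of shared regions 407 bp.

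Heterozygosity for C313Y, a change at a cysteine of AIRE, was accompanied by 183 gained and 80 lost genes. Among gained genes the widest peaks were at Gm3739, Flrt1, a cell adhesion and axon guidance gene, the neuronal adhesion gene Amigo1, Cacng1, a calcium channel subunit of muscle, Filip1l, the synaptic phosphatase Synj1, the rhodopsin kinase Grk1, Cass4, Clec2i and Spred2. The lost genes with the widest peaks were the microtubule-binding genes Clip2 and Clasp2, the connexin Gja5, Ripor3, the collagen chaperone Fkbp10, the sulfate transporter Slc13a1, Gm10058, dermatopontin Dpt, C1s2 and Mgst1. The gained peak at Amigo1 (chromosome 3, gene 108186289 to 108192286) spanned 108186241 to 108186625 in heterozygote replicate 2. The lost peak at Clip2 (chromosome 5, gene 134489383 to 134553767) spanned 134552200 to 134552808 in wild-type replicate 1. Flrt1, Amigo1, Cacng1, Grk1 and Cass4 each had a peak in all 4 mutant libraries of the other contrasts and in 2 of their 4 wild types.

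Across the genome, C313Y heterozygotes gained 5365 regions and lost 1628, 6993 in all, against 5463 and 4758 for the other pairings. Genes in both directions came to 263, against 284 and 223, so in genes the total for genotype lay between the mixed pairs. The smaller direction, 80 lost genes, exceeded that of both mixed pairings (33 and 61), and regions in both directions exceeded both. With the 55861 widest peaks of each list, 89 genes were lost, fewer than the smaller direction of the mixed pairings (100 and 94). Regions in both directions then came to 5946, against 4823 and 4189. The share near gene ends was 8.67% of gained, 6.63% of lost and 35.3% of shared regions, and gained exceeded lost (odds ratio 1.34, Fisher's exact p = 0.00847). Wild-type replicate 1 stood apart from its partner, with 3.27% against 2.23% of peaks on X. Without it 9442 regions were gained and 9840 lost, and without wild-type replicate 2 27714 were lost. Peaks at Y-linked genes were found at 1 and 3 of 4 genes in the heterozygotes and at 0 in both wild types. Peaks at Xist (3 and 0 against 3 and 1) and peaks on the whole Y chromosome (58 and 90 against 200 and 45) did not follow genotype.

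Olfactory receptor genes were again rarely gained, 1 of 1083 in C313Y heterozygotes against 2.36% of all genes at risk (Fisher's exact test, adjusted p = 2.12e-09). Both mixed pairings also had this shortfall (Fisher's exact test, adjusted p = 1.49e-12 and 1.98e-07), so it was not particular to genotype. Fibroblast and mural genes were lost in 2 of 3 cases, the proteoglycan Dcn and the receptor Pdgfra (Fisher's exact test, adjusted p = 0.00360), while Pdgfrb of the same list was gained. With lists of equal length 1 of 2 was lost and the call ended (Fisher's exact test, adjusted p = 0.265). Corneocyte-like genes gained 2 of 6, Dsg1a and the keratinocyte surface protein gene Lypd3 (Fisher's exact test, adjusted p = 0.131), and vomeronasal receptors 1 of 348 (adjusted p = 0.0698). The latter passed with lists of equal length (0 of 350, Fisher's exact adjusted p = 0.0369) and in both mixed pairings (adjusted p = 0.00128 and 0.0481). Traf1 was the one gained NF-kB gene. No member of the Aire-induced antigens (0 of 16), of the Fezf2-dependent antigens (0 of 6) or of mTEC identity (0 of 4) was gained, and none was lost. T cell, B cell, dendritic and endothelial markers gained 0 of 11, 0 of 6, 0 of 6 and 0 of 6.

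C442G heterozygotes gained 194 genes and lost 63. The strongest gained peaks were at Adcy4, an adenylate cyclase, the olfactory receptor Olfr90, the retinal photoisomerase gene Rgr, Gm33153, D830030K20Rik, Gm3558, the phosphatase subunit Ppp2r2c, the axon guidance receptor Robo3, the neuronal splicing regulator Ptbp2 and Zp3. Zp3 encodes a protein of the oocyte coat and belongs to the Aire-induced antigens. Its gained peak (chromosome 5, 135987451 to 135987651 in replicate 1, gene 135980105 to 135988624) was absent from all 8 libraries of the other contrasts. Lost genes included Gm44064, Ms4a15, Gm11213, the sperm gene Rimbp3, the transcription factor Foxc2, Lypd3, Nudt19, the growth factor binding protein gene Igfbp5, and the neighbours Draxin and Mad2l2, which share 1 peak. Lypd3 was thus lost here and gained with C313Y. The highest-ranked peaks at Nudt19 lay at opposite gene ends in the 2 wild types, and those at D830030K20Rik did not overlap between the 2 heterozygotes.

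In total C442G heterozygotes gained 11446 regions and lost 1628, while 65032 were shared by all 4 libraries. Both directions together came to 13074, against 5394 and 5229 for the other pairings, and genes to 257 against 187 and 170. With lists of 93659 peaks each, 5165 regions were gained and 3810 lost (4909 and 4980 for the mixed pairs), and genes turned to 77 gained and 195 lost. Of gained regions 4.85% lay near gene ends, against 8.17% of lost (odds ratio 0.573, Fisher's exact p = 1.47e-07) and 21.1% of shared regions (odds ratio 0.190). All 4 Y-linked genes had a peak in both heterozygotes and none in either wild type, and peaks at Xist numbered 2 and 1 against 4 and 4. Sex-linked signal therefore separated the C442G libraries exactly as genotype did.

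Of the gene groups in the C442G contrast, with the sex-linked difference between its libraries, 4 of 1083 olfactory receptors were gained (0.369% against 2.70% of all genes at risk, Fisher's exact test, adjusted p = 5.59e-08). Mixed pairings showed this as well (Fisher's exact test, adjusted p = 0.000232 and 1.10e-06). With all protein-coding genes as background neither this call nor that of vomeronasal receptors passed. Vomeronasal receptors gained 0 of 348 (Fisher's exact test, adjusted p = 0.00360), which did not pass with lists of equal length (adjusted p = 0.527). No other list passed. Aire-induced antigens gained 1 of 13 (Zp3), caseins 1 of 4 (Csn3), cytochromes P450 1 of 54 (Cyp1a1), serpins 1 of 32 and homeobox genes 1 of 11 (Hoxd4). Aire-induced antigens and homeobox genes, with lists of equal length, had 1 gain each, and caseins, cytochromes P450 and serpins 0. Lost members with all peaks were Lypd3, Serpina10 and Hoxb3. Markers of T cells (0 of 13), dendritic cells (0 of 3), B cells (0 of 3), fibroblasts (0 of 3), endothelium (0 of 4) and cortical epithelium (0 of 3) were not gained. Over the 3 contrasts 6 of 168 list tests passed, and the mixed pairings gave 3 and 5.

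**Figure D4:**
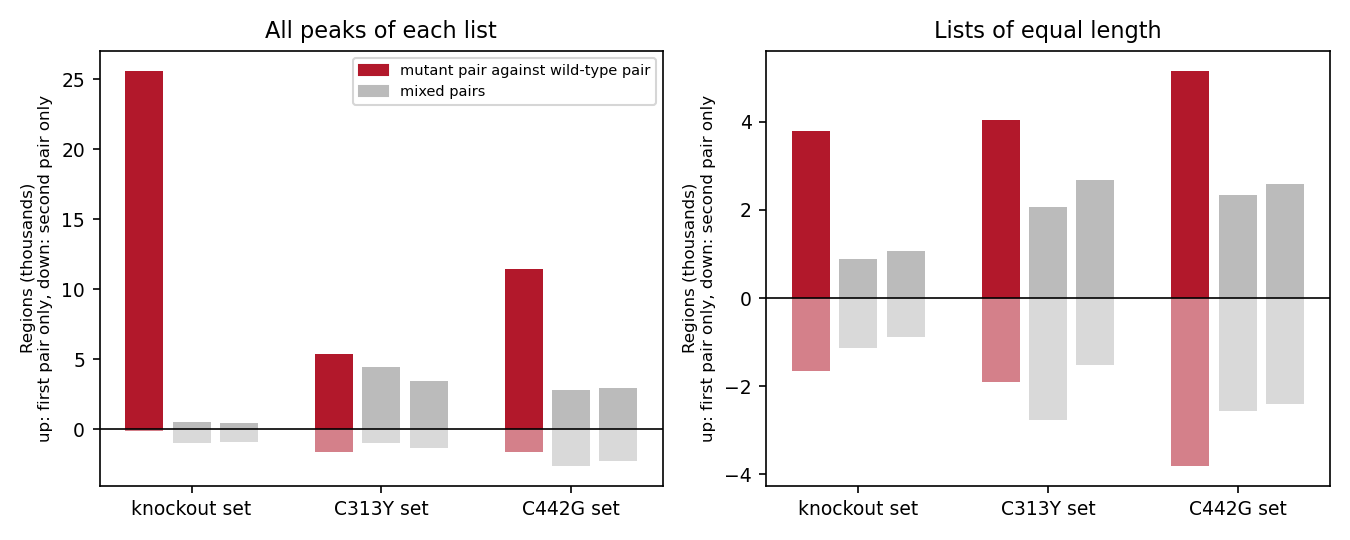
Regions, in units of 1000, called in both libraries of one pair and in neither of the other, for the 3 pairings of each contrast, with all peaks (left) and with lists of equal length (right). Red bars set mutants (up) against wild types (lighter, down) and grey bars set mixed pairs against each other; in the knockout 25625 regions were gained and 107 lost with all peaks, 3791 and 1662 with equal lengths.

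Whether the Aire genotypes shared altered regions was examined on 228401 merged regions of all libraries. Knockout and C313Y gains shared 1838 regions, against 587 expected for independent sets, a ratio of 3.13, and mixed pairings reached ratios up to 3.61. Knockout and C442G gains shared 1986 (1274 expected, ratio 1.56, mixed pairings up to 2.37), and C313Y and C442G gains 312 (264 expected, ratio 1.18, mixed up to 1.94). The sizes of these gained overlaps were thus within what mixed pairs gave. Knockout and C313Y losses shared 4 regions (0.705 expected, ratio 5.68, mixed up to 3.61; Fisher's exact adjusted p = 0.00724), a ratio of 1.01 with lists of equal length. Of C313Y and C442G losses 24 were shared (11.6 expected, ratio 2.06, mixed up to 1.94; Fisher's exact adjusted p = 0.00224). Direction was also compared. Of regions gained with C313Y, 312 were also gained and 25 lost with C442G. Of those lost with C313Y, 71 were gained and 24 lost with C442G, so these more often went the opposite way. The odds ratio of same against opposite direction was 4.20 (Fisher's exact adjusted p = 2.94e-05, mixed pairings up to 2.54). On autosomes alone, added after seeing the data, the odds ratio was 4.10. Peaks at Y-linked genes were found in mutants and not in wild types of both contrasts. They lay at 4 of 4 genes in both C442G heterozygotes and at 1 and 3 of 4 in the C313Y heterozygotes. Xist followed genotype in C442G alone, and a part of sex in this association of directions was not tested. For the knockout and C442G this odds ratio was 35.8 (Fisher's exact test, adjusted p = 0.0608), not past the threshold with all peaks. With lists of equal length within each contrast, 66 regions were gained in both, 14 lost in both, 5 lost in the knockout and gained with C442G and 0 the reverse (odds ratio 351, Fisher's exact adjusted p = 9.18e-12, mixed up to 4.20). The shared gains then fell below the 114 expected (ratio 0.578), while mixed pairings reached 0.303 at most. For the knockout and C313Y the odds ratio was 10.7 with all peaks (Fisher's exact test, adjusted p = 0.00724) and 1.253 with equal lengths (adjusted p = 0.581).

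At the level of genes, 115 regions but 1 gene, Cnga2, were gained in all 3 contrasts, and no region or gene was lost in all 3. Cnga2 (chromosome X, 71991849 to 72010218), the cyclic nucleotide-gated channel of olfactory neurons, had a peak in 6 of 6 mutant and 0 of 6 wild-type libraries. It was chosen after its values were seen. In a test of single genes over the 3 contrasts, added after seeing the data, Cnga2 alone reached the smallest p of the design (exact permutation p = 0.00926). By this test 17 of 5980 genes and 1027 of 209767 regions had an unadjusted p under 0.05, and none passed Benjamini-Hochberg adjustment. The smallest p of the design can pass adjustment only if a large share of all genes or regions reach it. It was reached by 1 gene and 115 regions, so this test could hardly pass any single gene or region. Knockout and C442G shared 41 gained genes, knockout and C313Y 48, and C313Y and C442G 3. The number of mutant libraries with a peak exceeded that of wild types by at least 4 of 6 for 148 genes, and the reverse held for 1 gene, Etl4 (2 mutant and 6 wild-type libraries). With lists of equal length these counts were 16 and 13.

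Base-pair overlap between lists separated genotypes most in the knockout contrast. The mean Jaccard index was 0.437 within genotypes and 0.289 ± 0.0160 (SD over 4 pairs) between them, and this difference of 0.148 fell to 0.0683 with lists of equal length. For C442G it was 0.531 within and 0.497 ± 0.0126 between, and for C313Y 0.434 within and 0.423 ± 0.0473 between, a difference inside the spread of pairs. Lists of different contrasts overlapped by 0.343 on average. The knockout lists overlapped the C442G wild types by 0.406 to 0.449, nearly as much as each other (0.451). Their own wild types overlapped them by 0.270 to 0.309, the C313Y lists by 0.287 to 0.374 and the C442G lists by 0.197 to 0.266. The separation in the knockout contrast thus cannot be read as genotype alone.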

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

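The tests of list length and of regions away from gene ends were chosen after the results they bear on had been seen.

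Sex-linked signal stood out in data that the comparisons did not use. Both C442G heterozygotes had peaks at 4 of 4 Y-linked genes (Kdm5d, Eif2s3y, Uty and Ddx3y), against 0 in both wild types. Knockout replicate 2 had 4 such genes, against 0 in replicate 1. C313Y heterozygote replicate 3 had 3, against 0 in both wild types of that contrast. Opposite calls between contrasts were seen at 32 genes, gained in both libraries of one contrast and lost in both of another, and this difference was not tested. Among them Thy1, Bmp8b and Ly6k were gained in the knockout and lost with C442G (chosen after their values were seen).

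The first pattern was the excess of peaks in the 2 knockout libraries over their wild types. With lists of equal length, changed regions still came to 2.69 times the higher mixed pairing, past the bound for list length as the whole cause. Each mixed pair joins 1 long and 1 short list. A trace of length left after cutting would thus show in the genotype pairing alone, and this test cannot decide. Among regions away from gene ends that changed in both contrasts, 64 were gained in both and 8 lost in both. A further 4 were lost in the knockout and gained with C442G, and 0 the reverse (odds ratio 244). A common move between gene ends and distal regions is argued against for these few regions only. Lower detection in the wild-type libraries of this contrast remains open, since 66.7% of the gained regions had a peak in both wild types of another contrast. A peak in at least 1 other wild type was found for 86.9% of gained regions and 39.2% of regions found in 1 knockout library alone. Regions called in both knockout libraries can be found more often in any list, so the comparison with 39.2% cannot decide. An effect shared by Aire mutants may also contribute, the odds ratio over all regions being 351 with equal lengths, although few regions carry it and library quality that moved with genotype in both contrasts would give the same.

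A second pattern was the gain of regions in C442G heterozygotes. With equal lengths changed regions came to 1.80 times the higher mixed pairing, past the bound for list length as the whole cause. Here too each mixed pair joins 1 longer and 1 shorter list, so this test cannot decide on length. Sex and genotype cannot be told apart here, because both heterozygotes had peaks at the Y-linked genes and neither wild type did. A test on autosomal regions that separated replicates 2 from replicates 1 in the knockout contrast found 9 gained and 1 lost with C442G against 10 and 1 (odds ratio 0.905, Fisher's exact p = 1), too few to decide. An effect of the C442G allele may be present, and the design does not separate it from sex.

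The third pattern was the position of gained regions away from gene ends. If gained regions were weak peaks, matching them by rank with shared regions should remove the gap in the share near gene ends. In the knockout the matched gap was -16.1 percentage points, against -36.9 unmatched, so peak strength may account for part and is argued against as the whole cause. In C442G the matched gap was -6.23 percentage points, between the bounds set in advance, so strength and position cannot be told apart there. A lower signal in wild-type libraries that affects distal regions beyond rank was not tested.

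Of 100 label assignments within contrasts, 2 gave as many genes open in more mutant than wild-type libraries as the real one (148 genes, highest other 176). With all peaks this was fewer than the bound set in advance for chance assignment of labels. The lists also differed in length, so chance was not excluded. The highest other kept knockout and C442G labels and exchanged C313Y libraries, placing the 2 longer lists of that contrast on the mutant side. For genes open in fewer mutant libraries (1 gene) the reference was the same set of counts (highest other 176, median 21), and all 100 gave as many. These counts were not made for that direction alone, so this comparison cannot decide. With lists of equal length 21 of 100 gave as many as the 16 genes found, with 38 as the highest other, so the count then did not exceed chance.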

How the results depend on the processing

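Gene bodies, autosomes only, the widest N peaks for C313Y, comparisons between contrasts that joined these to the strongest N peaks of the other 2, tests of single genes and regions and the alternatives for the peak at Aire were chosen after seeing the data.

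Of 323 values of the main results under alternatives, 187 kept their direction and their side of the threshold or moved little, and autosomes only and all sequences moved none of the counts of gained and lost regions and genes by over 1.5 times and ended no overlap between contrasts. Of calls on genes selected for naming, 51 moved and 45 did not at a −log10 q of at least 3, 50 and 46 with the strongest N peaks, 5 and 31 with the widest, 49 and 83 in gene windows of 500 bp and 61 and 71 in those of 2500 bp, and none changed direction. The stricter threshold and the strongest N peaks were not run for the C313Y lists, which hold positions only. Where no reason is given below, the cause was not tested. Depth is unknown, and it limits every call of absence.

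With a replicate block over the 5 same-numbered pairs, peak number differed by 0.78 and covered length by 0.78 on the log2 scale (exact sign-flip p = 0.0625 for each, the smallest 5 pairs allow). Deviations of same-numbered libraries had correlations of 0.00366 in the knockout and 0.00394 in the C442G contrast, so the numbers were not taken as pairs. Sex-linked signal did follow the number in the knockout contrast. Peaks lay at 0 of 4 Y-linked genes in both replicates 1 and at 4 and 3 in replicates 2.

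At a −log10 q of at least 3, which leaves fewer peaks, the knockout had 14575 gained and 39 lost regions and 3 lost genes, and C442G 7350 and 706 regions. Jaccard differences within minus between genotypes were 0.202 in the knockout and 0.0479 in C442G. The odds ratio of shared gains in the knockout and C442G was 1.07, that of shared losses in the knockout and C313Y 2.42, and that of same against opposite direction 31.6 for the knockout and C313Y, and all 3 calls ended (Fisher's exact p = 0.0790, 0.344 and 0.0871). Same against opposite direction for the knockout and C442G was 142 (Fisher's exact p = 0.0213, a call not made with all peaks).

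With the strongest N peaks, which equalises list length, the knockout had 3791 gained and 1662 lost regions and 173 gained and 339 lost genes, and C442G 5165 and 3810 regions and 77 and 195 genes. Passing gene lists numbered 1 in the knockout and 1 in C442G, genes open in more mutant libraries 15 and in fewer 10, and the Jaccard difference of the knockout was 0.0683. Shared gains and losses of the knockout and C442G turned to odds ratios of 0.617 and 0.379, and same against opposite direction rose to 351. With equal length within each contrast, C313Y by width, these were 0.565, 0.348 and 351 (shared gains 0.578 and losses 0.356 of the number expected, mixed pairings at most 0.303), concordant genes 16 and 13, shared gains of C313Y and C442G 1.05, shared losses of the knockout and C313Y 1.01, and their same against opposite direction 1.253, and the last 3 calls ended (Fisher's exact p = 0.575, 0.910 and 0.452).

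With at least 50% of a region covered, 161 regions were lost in the knockout, shared losses gave odds ratios of 3.43 with C313Y and, reversed, 0.980 with C442G, same against opposite direction 2.44 for the knockout and C313Y, and shared gains of C313Y and C442G 1.03, with Fisher's exact p of 0.119, 1, 0.298 and 0.661. In windows of 500 bp the knockout gained 5044 regions, C313Y gained 1623 and lost 495, and C442G gained 3855. Odds ratios there were 1.07 for shared gains and 1.73 for shared losses of C313Y and C442G, 1.09 for shared gains of the knockout and C442G and 4.88 for same against opposite direction of the knockout and C313Y, and these calls ended (Fisher's exact p = 0.535, 0.0635, 0.158 and 0.0583).

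Presence in at least 1 library, a looser rule, gave 81439 gained and 8225 lost regions and 2291 and 169 genes in the knockout, 29894 and 35719 regions and 730 and 708 genes in C313Y, and 47607 and 18901 regions and 688 and 397 genes in C442G. Against all 6 wild-type libraries, a stricter rule, the knockout had 3348 and 24 regions and 53 and 3 genes, C313Y 1002 and 22 regions and 22 and 0 genes, and C442G 0 lost regions and 115 and 1 genes.

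Gene windows of 500 bp gave 10 lost genes in the knockout and 2 genes open in fewer mutant libraries, and windows of 2500 bp gave 3 such genes and 4 passing lists in the knockout. Gene bodies gave 4 passing lists in the knockout, 1 in C313Y and 35 lost genes in C442G. With all protein-coding genes as background 0 lists passed in C442G.

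Leaving out 1 library loosens the rule for gained and lost, so these counts rise by construction. In the knockout gained regions ranged from 31857 to 58001, lost regions from 198 to 4937, gained genes from 1568 to 1851 and lost genes from 15 to 98. In C313Y the ranges were 9442 to 23067, 2484 to 27714, 318 to 595 and 134 to 525, and in C442G 18364 to 32980, 3597 to 11026, 379 to 539 and 146 to 245. Passing lists ranged from 4 to 6, 2 to 9 and 2 to 6. The log2 difference over 3 contrasts ranged from 0.52 to 0.66 for peak number and from 0.54 to 0.69 for covered length. Without C313Y heterozygote replicate 2 or its wild-type replicate 2 neither passed (exact permutation p = 0.130 and 0.130 for peak number, 0.0556 and 0.0648 for covered length).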

Other observations

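The width comparison at Aire was chosen after the widths had been seen.

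Of 3 regions near Aire called in all 12 libraries, 2 were wider in mutants than wild types in 3 of 3 contrasts. The region 78046194 to 78047024 on chromosome 10 differed by 0.70 on the log2 scale. The region 78018652 to 78019119 differed by 0.67, and the region at the gene end by 0.18 (wider in 2 of 3 contrasts). These widths prompted the comparison, so no p-value is given. Over all 18634 regions called in the 12 libraries the median difference was 0.22, and the first region stood above 91.9% of them, the other above 90.9% and the gene end above 42.4%.

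Of the 41 genes gained in both the knockout and C442G contrasts 5 are described here, and no shared function was tested. Pdcd1lg2, which encodes a ligand of the PD-1 receptor, had a peak in 5 of 6 mutant and 0 of 6 wild-type libraries, and the scavenger receptor Marco in 4 and 1. Lhb, the luteinizing hormone subunit, and the tachykinin Tac4 each had one in 4 and 0. The endocrine transcription factor Rfx6 had one in 4 and 1. Gains in both the knockout and C313Y included the desmosomal gene Dsg1a, the co-receptor Cd14 and the iodide transporter Slc5a5, each with 6 of 6 mutants and 2 wild types. These genes were chosen after their values were seen.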
